A study of Picea glauca with 26 samples.

How the data were processed

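The series compared shoot tips, needles and secondary stems of white spruce by 2-colour hybridisation. It held 26 comparisons in 4 experiments: 7 in the SD course, 6 in the LD course, 7 between LD and SD on the same day, and 6 between tissues. Each comparison had 4 arrays, 104 in all. Per the labels' protocols, total RNA was amplified to antisense RNA and labelled with Alexa 555 or Alexa 647, and 2 of the 4 biological replicates of each comparison had the dyes exchanged. Whether the replicates of different comparisons came from the same plants is not stated in the labels, and the p-values measure the spread between these arrays.

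The deposited scanner files hold raw spot intensity at 635 and 532 nm, per the file headers, written by GenePix Pro 6.0.1.27 from a GenePix 4000B scanner with no normalization applied. Each array held 24288 spots, of which 2172 were control spots; 11040 probes were printed at least 2 times, 18 of them 4 times. The files also hold a quality flag per spot (other than an intensity or a log2 value), set by the scanner software, per the file headers: -100 for bad spots (10285 over all arrays), -75 for absent spots (64873) and -50 for spots not found (1097330). The spots name 9688 contigs from 16 libraries but pair no clone with a gene name. Only 22 probes carry a gene name, and the meaning of the parts pt, SKN, SMT, SCL, Hb, PTO and SNF is not given in the sources used here. The arrays of 2 comparisons, SD day 3 and low temperature, each had 1 array file in which a block carried the clone names of another block, 488 and 486 spots; the intensities followed the position (r with the median array 0.99 and 0.84) rather than the printed names (0.12 and 0.22), so names were taken from the position.

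The authors' deposited table of processed values holds log2 ratios, as far as the values show; the labels used here do not state how they were made, and its scale is unknown. Its 11036 entries have running numbers and no probe names. Set against the scanner values after the data were seen, with several orders tried, they followed the clones in print order with 1 row for each pair of spots, 11018 clones in all, and without the 22 gene-named probes. In this order the 20 columns of the time courses and of LD and SD correlated with the ratios computed here with r between 0.73 and 0.95, and shifting by 1 row gave r of at most 0.03 in size. Column medians lay between -0.04 and 0.06, so the columns were centred near 0. The slope on the ratios computed here differed between columns: in the SD course it was 1.48 at day 1, 1.85 at day 3, 0.66 at day 70 and 0.53 after low temperature, in the LD course 1.35 at day 1 and 0.69 at day 70, and between LD and SD 1.09 at day 0 and 1.22 at day 70. The 6 tissue columns ran opposite to the direction of the labels' dye notes (r between -0.94 and -0.90). Those notes name array files by a prefix that the tissue files do not have, so the direction was also checked from the channel levels. For each of the 16 tissue arrays with shoot tip, the normalized log2 level of each channel was correlated over probes with the mean level of SD buds of the same day in the SD course. The channel that the notes call shoot tip was the closer on 16 of 16 arrays, and also on all 16 with the SD channel of the direct comparison as reference. The direction of the notes was therefore kept. This check was added after the data were seen. These values were used only to compare columns, and no clone's value was taken from them.

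Foreground means were corrected with the normexp method of limma 3.58.1 in R 4.3.3, offset 50, against background medians. Log2 ratios were normalized within each array by loess with control spots at weight 0, spots flagged -100 were left out, and spots of a probe were averaged. Ratios were turned to the named direction by the dye notes, LD over SD arrays to SD over LD. For each experiment a linear model had 1 coefficient per comparison and a dye effect for each probe (1 per day in the tissue experiment), followed by empirical Bayes moderation; differences between SD and LD were contrasts in a joint fit of 52 arrays. P-values were adjusted by the Benjamini-Hochberg method within each comparison over 11040 probes, and a probe was called changed at an adjusted p under 0.05. Tested on simulated data for SD day 7 over SD day 0, with 10631 probes of which 200 were changed, the fit called 65 of 100 probes changed 1.5-fold and 90 of 100 changed 2-fold, with 6 false calls among 161. The simulated errors were normal and independent between probes and arrays, with the real probe spreads, and only this comparison was changed. These numbers therefore do not measure the error rate on the real arrays.

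The design, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 5 probes with the largest rise and the 5 with the largest fall in the main comparisons, and 3 each way in the others, among probes with an adjusted p under 0.05, the same sign on all 4 arrays and a gene name; for differences the arrays of both sides had to be separate. Few probes meet it, since only 22 carry a name; a gene named once was followed through other comparisons, and other gene-named probes are given where they fall outside the rule, chosen after their values were seen. The clones named are among those with the largest changes. The 25 gene lists fixed in advance matched 0 probes by name and were not tested, with their alternatives. Gene families by name part, and the 6 groups of probes at least 2-fold higher or lower in a tissue than in both others at day 14, were formed after the data were seen. These groups were tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the 6 groups.

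Alternatives fixed in advance were no background correction, median centring in place of loess, scaling of ratios between arrays, probes above background only (foreground over background median plus 2 background SDs), no dye term, each comparison on its own arrays, each array left out in turn, scan date as a random block, and the tissues of a day fitted jointly. The fits of a comparison on its own arrays also had no dye term. For the agreement of direct and indirect differences, Spearman's rho and probes above background were used. Added after the data were seen were fits without the 2 tissue arrays with most spots not found, without the 2 arrays with misnamed blocks, with the direct day 70 arrays of each dye orientation alone, and with the tissue direction of the authors' values. Setting the authors' values beside the named genes was not run, because the gene-named probes are not in that table. Scan dates gave between 6 and 8 batches per experiment. A batch held at most 3 arrays of a comparison, too few for tests within batches, so scan date entered only as a random block, where the consensus correlation lay between -0.10 and -0.05. The share of probe spots above background had a median of 74.0% per array and a range of 33.5% to 90.6%. Figures were drawn with matplotlib.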

Results

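Apical bud formation was followed in white spruce (Picea glauca), a conifer whose shoot tips stop growing and set buds when days become short. Plants that were 2 years old spent 6 to 8 weeks in long days with 16 hours of light. Part of them then moved to short days (SD) with 8 hours of light, and others stayed in long days (LD). Expression was measured on 2-colour arrays of 11040 probes. Of these, 11018 were clones known here only by clone number and 22 carried a gene name beginning with pt. The 26 comparisons fell into 4 experiments. In the SD course, buds of days 1, 3, 7, 14, 28 and 70 and after low temperature were set against SD day 0. In the LD course, shoot tips of the same 6 days were set against LD day 0. LD and SD were also hybridised together on 7 days including day 0. The last experiment set shoot tip, needle and secondary stem against each other at SD day 14 and day 70. Each comparison held 4 arrays from 4 biological replicates, 2 of them with the dyes exchanged, and this number of arrays limits the precision of every value. The share of probe spots that the scanner software did not find had a median of 38.6% over the 104 arrays, with a range of 26.1% to 82.7%. The highest shares lay in the tissue arrays of day 70 (46.6% to 82.7%), while those of day 14 had 26.1% to 41.7%. Duplicate spots of an array correlated over probes with r between 0.80 and 0.99.

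The short-day course asked which transcripts changed while buds formed. After 70 days the 3 probes named ptSKN were all higher than at day 0, and both ptSMT probes were lower. Among the gene-named probes with the same sign on all 4 arrays, the largest rises were ptSKN3 with a log2 ratio of 1.61 ± 0.35 (SD, n = 4 arrays, adjusted p = 4.73e-07), ptSKN1 with 0.97 ± 0.63 (adjusted p = 3.49e-05) and ptMYB7, of the MYB family of transcription factors, with 0.78 ± 0.83 (adjusted p = 0.00088). ptSKN2, with a value on only 3 arrays, stood at 1.11 (adjusted p = 2.16e-05). ptSCL1 rose by 0.50 ± 0.33 and ptCLV1-2 by 0.42 ± 0.10. The largest falls were those of ptMYB1 at -1.19 ± 0.57 (adjusted p = 1.26e-05), ptSMT1 at -0.92 ± 0.42 (adjusted p = 6.55e-07), ptLIM3, of the LIM-domain protein family, at -0.65 ± 0.31 (adjusted p = 4.97e-05), ptSMT2 at -0.35 ± 0.06 and ptPTO at -0.32 ± 0.18. In total 8 of the 22 gene-named probes rose, 5 fell and 9 did not pass the test. Of the 6 ptMYB probes 1 rose and 1 fell, and of the 3 ptLIM probes 1 rose and 1 fell. Without array 3 ptMYB7 stood at 0.44, and without array 4 ptSCL1 was not called (0.33). ptPTO was not called when any 1 of arrays 1 to 4 was left out (-0.27, -0.31, -0.36 and -0.33). Here and below, p-values rest on a spread shared by all arrays of an experiment, while ± gives the SD of 4 arrays alone. Over all results, 27 of 135 gene-named calls with the same sign on all arrays were lost with each comparison fitted on its own arrays without a dye term.

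Changes were few in the first days and spread to most of the array by day 70. The test called 182 probes at day 1, 71 of them up, and 158 at day 3, 85 of them up. At day 7 it called 801 probes (393 up, 408 down), at day 14 2055 (1097 up, 958 down), at day 28 4363 (2154 up, 2209 down) and at day 70 6674 (3328 up, 3346 down), which is 60.5% of the probes tested. Loess centred each array near 0 (median log2 ratio 0.0129 at day 70), so a near-equal split up and down is partly imposed. This holds for the other comparisons too, and a shift of most transcripts in the same direction could not be seen. ptSCL1 was the only gene-named probe called at day 7, at 0.53 ± 0.08 (adjusted p = 0.0314), and at day 14 it stood at 0.60 ± 0.16 beside ptMYB8 at 0.42 ± 0.22. By day 28 ptSKN3 had risen by 0.87 ± 0.29, ptMYB7 by 0.74 ± 0.21, ptSKN1 by 0.56 ± 0.26, ptSKN2 by 0.55 ± 0.31 and ptLIM1 by 0.52 ± 0.24. On the same day ptHb3 stood at -0.64 ± 0.25, ptSMT1 at -0.42 ± 0.24 and ptHb1 at -0.34 ± 0.31. At day 70 2233 probes were called with a change of at least 2-fold, 951 up and 1282 down. Clone MN5238798 had the largest rise at 6.40 ± 0.17 (adjusted p = 4.94e-12), and clone MN5165163 the deepest fall at -6.26 ± 0.22 (adjusted p = 9.87e-12). The call of ptSCL1 at day 7 was lost without any 1 of arrays 1 to 4 (0.49, 0.56, 0.53 and 0.54) and at day 14 without array 1 (0.52), and that of ptMYB8 without arrays 1, 2 or 3 (0.41, 0.45 and 0.33). At day 28 calls were lost without array 2 or array 4 for ptSKN1 (0.49 and 0.51), ptSKN2 (0.49 and 0.45) and ptLIM1 (0.47 and 0.46), without array 2 for ptSMT1 (-0.37), and without array 1 or array 3 for ptHb1 (-0.36 and -0.22). The count at day 1 was 91 and 67 without arrays 3 and 4, but 200 without array 2. Day 3 gave 31, 24 and 75 without arrays 2, 3 and 4, day 7 gave 123, 234 and 251 without arrays 1, 3 and 4, and day 14 gave 1018 and 907 without arrays 1 and 2. When all arrays of the course were scaled to an equal spread, day 1 gave 710 probes and day 70 gave 4225.

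**Figure D1:**
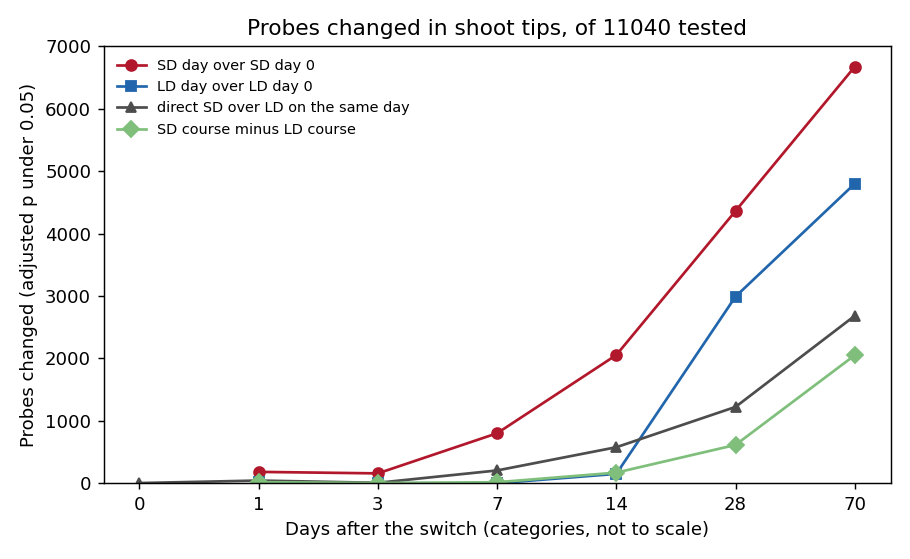
Number of probes with adjusted p under 0.05 (vertical axis) by day (horizontal axis, as categories) for SD over SD day 0, LD over LD day 0, SD over LD hybridised together, and the difference between the SD and LD courses. The SD course reached 6674 probes at day 70, the LD course 4800, the direct comparison 2683 and the difference of the courses 2051.

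Buds held for a further 3 to 4 weeks at 2 to 4 °C differed from day 0 in 7637 probes, 3865 up and 3772 down. The ptSKN and ptSMT probes stood on the same sides as at day 70: ptSKN3 was at 1.82 ± 0.69 (SD, n = 4 arrays, adjusted p = 4.09e-08), ptSKN1 at 1.03 ± 0.67, ptSMT1 at -0.78 ± 0.41 and ptSMT2 at -0.47 ± 0.32. Further rises were those of ptSCL1 (0.59 ± 0.54), ptMYB8 (0.58 ± 0.42) and ptHb2 (0.42 ± 0.54). ptMYB1 was the deepest fall at -1.07 ± 0.39 (adjusted p = 3.77e-05). Of the 22 gene-named probes 11 rose and 3 fell, and 5 of the 11 did not have the same sign on all arrays. Array 3 stood above the others for most of them: without it 6 rose and 5 fell, ptHb2 was not called (0.17) and ptSCL1 stood at 0.32. A test of low temperature against SD day 70 called 3953 probes, 1963 higher and 1990 lower after low temperature. That test cannot tell temperature apart from the added weeks, since no comparison held buds of that age without low temperature. In that test ptHb3 was 0.71 higher (SE 0.24, adjusted p = 0.0198) and ptMYB7 0.72 lower (difference -0.72, SE 0.27, adjusted p = 0.0363), although the arrays of the 2 stages overlapped for both probes. Neither was called when p-values were adjusted over the 22 gene-named probes alone. Scaled to equal spread, the same arrays gave 4357 probes over day 0 and 491 between the 2 stages.

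**Figure D2:**
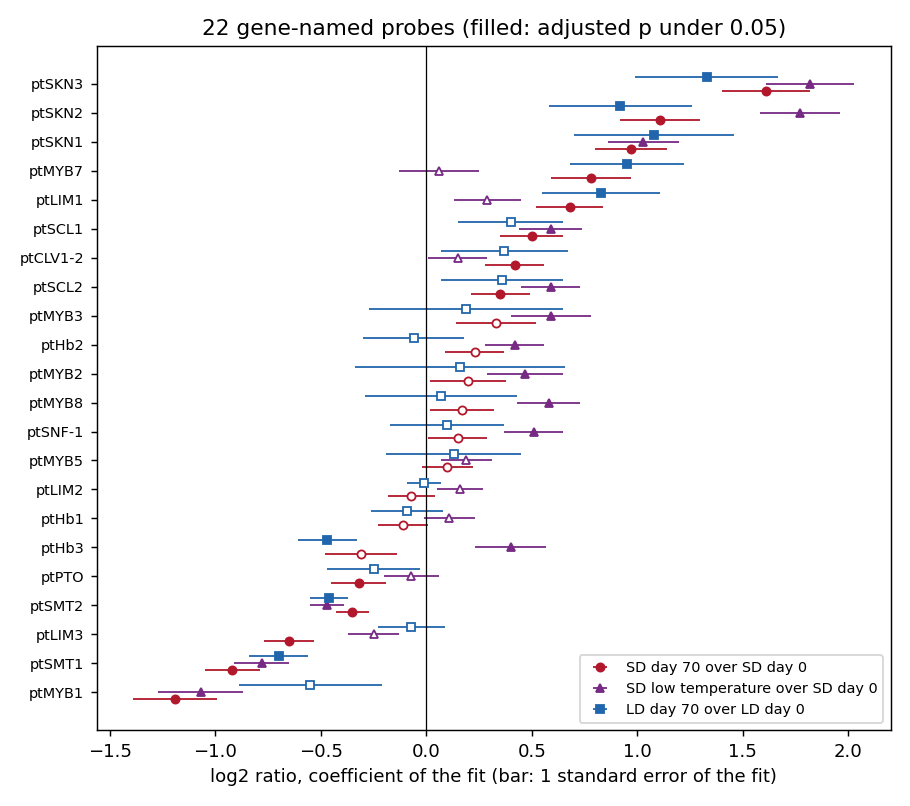
Log2 ratios of the 22 gene-named probes (horizontal axis, coefficient of the fit with 1 standard error) at SD day 70, after low temperature and at LD day 70, each over its own day 0; filled symbols passed adjusted p under 0.05. The ptSKN probes lie to the right and the ptSMT probes to the left in all 3, with ptSKN3 at 1.61, 1.82 and 1.33. Each point rests on 4 arrays, except ptSKN2 at SD day 70 and after low temperature and ptMYB2 at LD day 70, which rest on 3.

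The long-day course asked what changed with time in shoot tips that were not moved to short days. For the first 7 days almost nothing passed the test: 14 probes at day 1, and 0 probes at day 3 and at day 7 by limma, with 423 and 694 probes at an unadjusted p under 0.05. Scaling the arrays to equal spread gave 16 and 22 probes on those days. At day 14 150 probes were called, at day 28 2991 (1660 up, 1331 down) and at day 70 4800 (2381 up, 2419 down). Among gene-named probes with the same sign on all 4 arrays, the largest rises at day 70 were ptSKN3 at 1.33 ± 0.72 (SD, n = 4 arrays, adjusted p = 0.00377), ptMYB7 at 0.95 ± 1.03 and ptSKN2 at 0.92 ± 0.80. ptSKN1 was also called, at 1.08 ± 0.85 (adjusted p = 0.0258), but not with the same sign on every array. Those that fell were ptSMT1 at -0.70 ± 0.60 (adjusted p = 0.000583), ptHb3 at -0.47 ± 0.25 and ptSMT2 at -0.46 ± 0.25 (adjusted p = 0.000292). At day 28 the largest rises were ptSKN3 (1.25 ± 0.99), ptSKN1 (1.11 ± 0.79) and ptCLV1-2 (0.98 ± 0.53). The only gene-named fall called on that day was ptHb3 at -0.43. Clone MN5238798 was again far above day 0 at LD day 70, at 5.59 ± 0.61, and clone MN5165163 far below it, at -6.15 ± 0.59. At day 70 calls were lost without array 1 for ptMYB7 (0.64), without arrays 1, 3 or 4 for ptSKN2 (0.63, 0.99 and 0.93) and without array 4 for ptHb3 (-0.35). At day 28 they were lost without array 2 or 3 for ptSKN3 (1.03 and 0.97) and ptCLV1-2 (0.73 and 0.96), and without arrays 2, 3 or 4 for ptSKN1 (0.83, 0.98 and 1.26). That of ptHb3 was lost without array 1 or 4 (-0.35 and -0.36). The count at day 1 was 6, 8, 7 and 5 without arrays 1 to 4, and that of day 14 was 0, 9 and 0 without arrays 1, 3 and 4; scaling to equal spread moved day 70 to 2272.

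Long-day and short-day tips at day 70 had moved mostly the same way. Over all probes the log2 ratios of the SD and LD courses correlated with r = 0.79 at day 70, 0.70 at day 28, 0.50 at day 14, 0.10 at day 7, 0.15 at day 3 and -0.01 at day 1, across probes, which are not independent replicates. At day 70 1804 probes were up in both courses where independent lists would share 717.8, and 2021 were down in both where 733.1 would be shared. Only 14 were up in SD and down in LD, and 78 the reverse. The courses used different arrays, and the labels do not say whether they shared day 0 RNA.

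The difference between the courses asked what short days added. The test of SD minus LD called 17 probes at day 1, 4 at day 3, 16 at day 7, 170 at day 14 and 614 at day 28, and at day 70 2051 probes, of which 908 were higher and 1143 lower in SD. ptLIM3 was the only gene-named probe called at day 70, 0.58 lower in SD (difference -0.58, SE 0.20, adjusted p = 0.0385), with overlapping arrays. It was not called when p-values were adjusted over the 22 gene-named probes alone. ptSKN3, called in both courses, was not called in their difference. The counts up to day 28 changed by over 1.5 times when single arrays were left out. Day 1 gave 11, 1 and 4 without SD arrays 2, 3 and 4, and 1 and 8 without LD arrays 1 and 4. Day 3 gave 8 and 2 without SD arrays 1 and 3, and 2, 7 and 2 without LD arrays 1, 2 and 3, and day 7 gave 5 and 4 without SD arrays 1 and 2, and 9 and 2 without LD arrays 1 and 4. Day 14 gave 35 and 30 without SD arrays 1 and 2, and 100, 81, 78 and 84 without LD arrays 1 to 4. Day 28 gave 307 and 182 without SD arrays 1 and 3, and 296 and 371 without LD arrays 1 and 2. Scaling to equal spread left 94 probes at day 70.

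Direct hybridisation of SD against LD put both day lengths on one array. Before the switch, at day 0, 3 probes were called, with 742 at an unadjusted p under 0.05. This background is itself uncertain: it was 1, 19, 1 and 0 without arrays 1 to 4, 28 with scan date as a block and 77 with scaling to equal spread. At day 14 ptMYB7 was higher in SD with a log2 ratio of 0.81 ± 0.42 (SD, n = 4 arrays, adjusted p = 0.0212), ptLIM1 with 0.61 ± 0.21 and ptMYB8 with 0.48 ± 0.30. At day 28 ptMYB7 stood at 1.24 ± 0.57 (adjusted p = 0.000408), ptLIM1 at 0.96 ± 0.37 (adjusted p = 0.000368) and ptMYB1 at -0.96 ± 0.34 (adjusted p = 0.0076). The separate courses called none of the 22 gene-named probes in SD minus LD at day 14 or day 28. At day 28 their difference was 0.41 for ptMYB7 (SE 0.33), 0.02 for ptLIM1 (SE 0.32) and -0.84 for ptMYB1 (SE 0.40). By day 70 none of these was called in the direct comparison, with ptMYB7 at -0.15 and ptLIM1 at -0.19, and ptLIM3 alone among the gene-named probes was lower in SD, at -0.64 ± 0.43 (adjusted p = 5.97e-05). The counts were 43 probes at day 1, 7 at day 3, 205 at day 7 (150 up, 55 down), 577 at day 14, 1223 at day 28 (576 up, 647 down) and 2683 at day 70 (1241 up, 1442 down). Day 70 differed from day 0 in 1145 probes, among them ptLIM3 at -0.53 (SE 0.14, adjusted p = 0.018). The 4 arrays of day 70 parted by dye orientation: arrays of the same orientation correlated with r = 0.66 and 0.72, those of opposite orientation with r between -0.10 and 0.26. At day 14 calls were lost without arrays 2, 3 or 4 for ptMYB7 (0.74, 0.67 and 0.78) and ptLIM1 (0.55, 0.58 and 0.54), and without any 1 of arrays 1 to 4 for ptMYB8 (0.56, 0.57, 0.42 and 0.39). At day 28 that of ptMYB1 was lost without array 1 or 2 (-0.85 and -0.90). Without arrays 1 to 4 in turn, day 1 gave 28, 28, 10 and 5 probes and day 7 gave 30, 128, 64 and 108. Day 3 gave 0 without array 2 or 4, day 14 gave 236 and 254 without arrays 2 and 4, and day 28 gave 685, 584 and 689 without arrays 1, 2 and 3. Day 70 minus day 0 gave 744 without array 1 of day 0 and moved likewise without array 2 of day 0. Fitted on its 4 arrays alone without a dye term, so that the difference between orientations entered the spread, day 70 gave 0 probes. Scaling to equal spread gave 883.

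The direct ratios, less that of day 0, were set beside the difference of the separate courses. The arrays differ, but the labels do not say whether the RNA does, so the 2 estimates may not be independent. The difference of the courses correlated with the direct ratio of day 0 with r from -0.18 (day 3) to -0.03 (day 7), the sign that shared day 0 material would give. Replicate arrays agreed little at day 1, with a mean r between arrays of 0.07 in the direct comparison, 0.14 in SD and -0.06 in LD. Over probes the 2 estimates correlated with r = 0.54 at day 1, 0.53 at day 3, 0.58 at day 7, 0.62 at day 14, 0.66 at day 28 and 0.84 at day 70. Set against the direct ratios of the other days after day 0 instead, a comparison chosen after the data were seen, r reached at most 0.35, 0.44, 0.41, 0.46, 0.60 and 0.52 in the same order. Of the 2051 probes called in the difference of the courses at day 70, 2017 had the same sign in the direct comparison and 1514 were called there too, 1508 of them with the same sign. At day 28 the corresponding numbers were 614, 574, 297 and 293.

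The tissue comparisons asked which probes set shoot tips, needles and secondary stems apart. All tissue directions given here follow the dye notes in the labels, and the authors' deposited values run the other way in all 6 tissue comparisons, with r between -0.94 and -0.90. On all 16 tissue arrays with shoot tip, the channel that the notes call shoot tip correlated more closely over probes with SD buds of the same day in the SD course than the other channel did. The correlations at day 14 were 0.95 to 0.98 for the shoot tip channel and 0.83 to 0.90 for the other. The difference had a median of 0.0906 at day 14 and 0.0253 at day 70, where it ranged from 0.0047 to 0.159. By the dye notes, stem at day 14 was above needle for 19 of the 22 gene-named probes and below it for 1, and all 6 ptMYB, all 3 ptLIM and all 3 ptSKN probes were among the 19. Of the 19, 3 did not have the same sign on all arrays, and without array 2 17 were above and 2 below. The largest such ratios were ptMYB7 at 4.27 ± 1.22 (SD, n = 4 arrays, adjusted p = 3.04e-10), ptSKN3 at 3.95 ± 0.97 (adjusted p = 4.97e-08) and ptLIM1 at 3.44 ± 1.46, with ptSMT2 on the other side at -0.61 ± 0.17. Stem over shoot tip was largest for ptSKN1 (3.28 ± 1.01), ptSKN3 (3.11 ± 0.59), ptSKN2 (2.46 ± 0.51), ptHb1 (2.27 ± 0.26) and ptMYB7 (1.53 ± 0.38), and negative for ptMYB1 (-0.60 ± 0.44) and ptSMT2 (-0.50 ± 0.13). Shoot tip over needle was largest for ptMYB7 (2.61 ± 0.90), ptLIM1 (2.41 ± 1.09), ptSKN3 (1.87 ± 1.43), ptMYB5 (1.64 ± 0.63) and ptLIM3 (1.53 ± 0.42). At day 14 the test called 6551 probes between shoot tip and needle (3282 up, 3269 down), 5082 between stem and shoot tip (2560 up, 2522 down) and 6377 between stem and needle (3169 up, 3208 down).

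At day 70 the tissues differed in fewer probes by the test used here, on arrays with more spots not found. Shoot tip over needle called 3183 probes (1695 up, 1488 down), stem over shoot tip 1706 (763 up, 943 down) and stem over needle 2060 (803 up, 1257 down). The largest shoot tip over needle ratios were ptSKN3 at 3.22 ± 0.27 (SD, n = 4 arrays, adjusted p = 1.23e-05), ptMYB7 at 2.96 ± 0.48, ptLIM1 at 2.72 ± 0.60, ptCLV1-2 at 2.44 ± 0.62 and ptSKN1 at 2.39 ± 0.33, with ptSMT2 at -0.32 ± 0.20. Stem over needle was largest for ptMYB7 (3.81 ± 1.14), ptLIM1 (3.54 ± 1.17) and ptSKN3 (2.39 ± 1.44), and stem over shoot tip for ptHb3 (0.59 ± 0.42) and ptHb2 (0.43 ± 0.31). The tissue arrays of day 14 and day 70 shared no scan date and, by their name prefixes, came from different printed batches. For a single probe, change with time therefore cannot be told apart from a difference between array batches. Over all probes, the change of shoot tip over needle followed that of SD buds between these days in the SD course (r = 0.84, slope 0.77). This argues against array batches as its only source. The day 14 ratio itself correlated with the SD day 70 change (r = -0.66), so ratios shrunk on the day 70 arrays could give part of it. Stem over shoot tip gave r = -0.39 and stem over needle 0.49. Tests of day 70 against day 14 called 4348 probes for shoot tip over needle, 2147 for stem over shoot tip and 3619 for stem over needle. In these, the stem over shoot tip ratio of ptSKN1 was lower at day 70 (difference -2.33, SE 0.69, adjusted p = 0.021), as were those of ptSKN2 (-2.10, SE 0.25) and ptSKN3 (-1.99, SE 0.58), while that of ptSMT2 was higher (0.53, SE 0.15). The shoot tip over needle ratio was lower at day 70 for ptLIM3 (-1.44, SE 0.27), ptSMT1 (-1.12, SE 0.20) and ptMYB1 (-0.88, SE 0.20). The stem over needle ratio was lower for ptHb1 (-2.21, SE 0.28), ptMYB8 (-1.32, SE 0.32) and ptHb2 (-1.09, SE 0.14), with ptSMT2 higher there too (0.49, SE 0.15). Without the 2 day 70 arrays in which over 75% of the spots were not found, an alternative chosen after the data were seen, stem over shoot tip at day 70 gave 835 probes. Shoot tip over needle gave 1849 and 2058 without arrays 1 and 3, and stem over shoot tip 819 and 903 without arrays 3 and 4. Other settings moved the counts both ways. On their own arrays without a dye term stem over shoot tip gave 708 and stem over needle 1227. Scaling to equal spread gave 2968 and 3703, and a joint fit of the tissues 3562 for stem over needle. With scaling shoot tip over needle gave 4257 probes at day 70 and 4211 at day 14, so that comparison did not have fewer at day 70. Calls were lost without arrays 1, 3 or 4 for ptSMT2 in shoot tip over needle (-0.23, -0.30 and -0.30) and ptHb3 in stem over shoot tip (0.58, 0.48 and 0.46), and without array 3 for ptHb2 there (0.36). Of the changes with time in stem over shoot tip, those of ptSKN1 (-1.71 and -2.00) and ptSKN3 (-1.57 and -1.56) were lost without array 4 of day 14 or array 2 of day 70, and that of ptSMT2 (0.45 and 0.47) without array 4 of day 14 or array 1 of day 70. In stem over needle the change of ptSMT2 was lost without array 2 of day 14 or array 4 of day 70 (0.45 and 0.43), and that of ptMYB8 was -0.83 without array 2 of day 14.

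**Figure D3:**
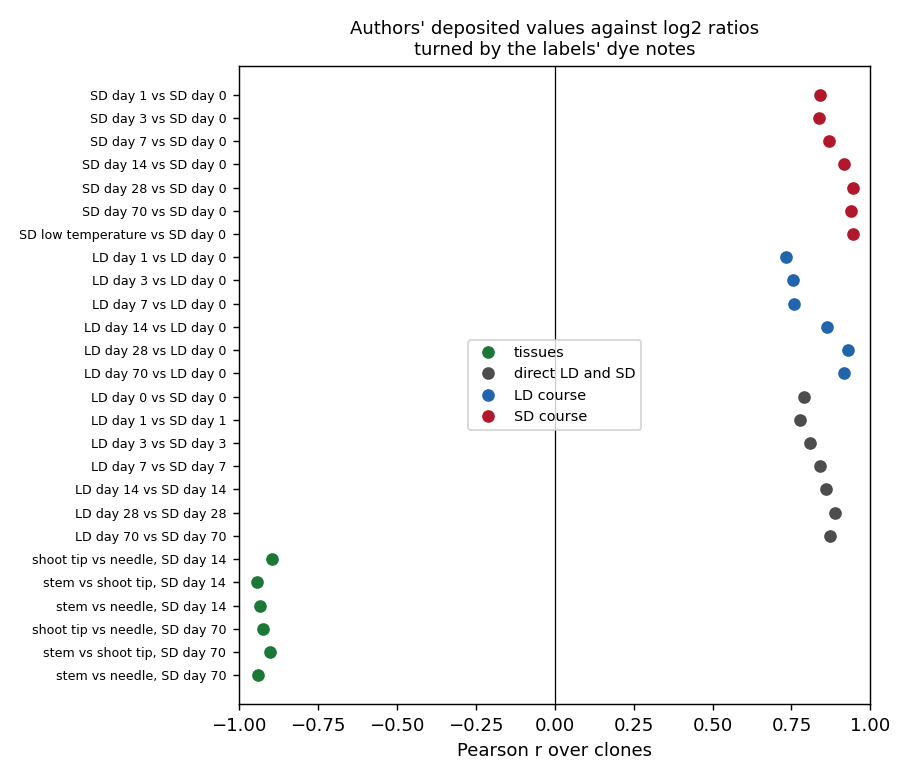
Pearson correlation over clones (horizontal axis) between the authors' deposited values and the log2 ratios computed from the scanner files, for each of the 26 comparisons. The 20 comparisons of the time courses and of LD and SD lie between 0.73 and 0.95 and the 6 tissue comparisons between -0.94 and -0.90.

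The 3 tissue ratios of a day are tied to each other, because stem over needle should equal stem over shoot tip plus shoot tip over needle. That sum correlated over probes with the measured stem over needle ratio with r = 0.98 at day 14 and 0.93 at day 70. The sizes did not match: the slope of the sum on the measured ratio was 1.11 at day 14 and 1.25 at day 70.

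Probes that stood apart in shoot tips at day 14 were then followed through the day-length courses, which used other arrays; these groups were chosen after the data were seen. By the dye notes, 236 probes were at least 2-fold higher in shoot tip than in both needle and stem, and at SD day 70 220 of them were lower than at day 0 and 6 higher, with a median log2 ratio of -2.11 (camera, adjusted p = 2.87e-41 with a preset correlation of 0.01, and adjusted p = 0.00128 with an estimated correlation). At LD day 70 190 of the 236 were lower and 1 higher, with a median of -1.51 (adjusted p = 0.0101 with an estimated correlation). A further 86 probes were lower in shoot tip than in both other tissues by the dye notes. Of these 72 rose and 3 fell at SD day 70, with a median of 1.68 (adjusted p = 0.00388 with an estimated correlation), and 75 rose and 0 fell at LD day 70, with a median of 1.60 (adjusted p = 0.0126 with an estimated correlation). At SD day 14 the medians were -0.17 and 0.05 (adjusted p = 0.697 with an estimated correlation for both), and at SD day 28 they were -1.16 and 0.90 (adjusted p = 0.00118 and 0.00422 with an estimated correlation). At LD day 28 the medians were -0.73 and 0.86 and did not pass (adjusted p = 0.0545 with an estimated correlation for both).

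**Figure D4:**
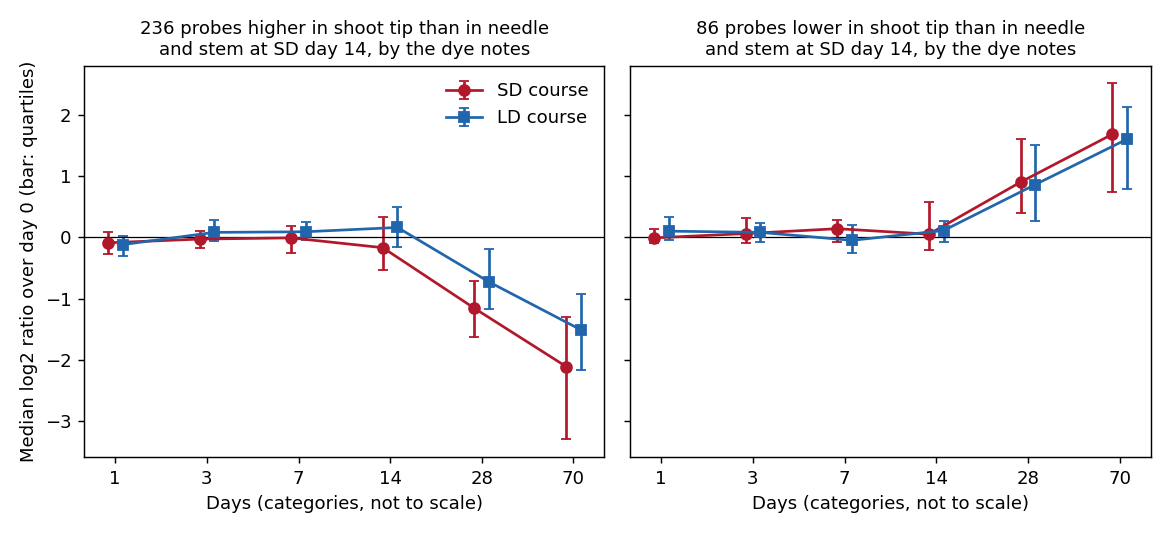
Median log2 ratio over day 0 (vertical axis, bars from the lower to the upper quartile of probes) by day (horizontal axis, as categories) in the SD and LD courses, for 236 probes higher and 86 probes lower in shoot tip than in needle and stem at SD day 14 by the dye notes. The group of 236 reaches -2.11 in SD and -1.51 in LD at day 70, and the group of 86 reaches 1.68 and 1.60.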

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

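The tests of partly turned dye notes, of the order of the authors' values and of the dye orientation by labelling and by scan date were chosen after the results were seen, as was the counting of regrouped arrays. The tests by channel level, dye effect, non-overlap of LD and SD arrays, shared day 0 RNA and dim spots were set before their own values were seen, but after the patterns were.

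Gene-named probes for which a single array lay far from the other 3 of its comparison were ptSKN1 in stem over needle at SD day 70 (3.80 on array 3, others 0.70 to 0.99), ptHb3 in the same comparison (1.46 on array 3, others 0.73 to 0.79), ptMYB7 in shoot tip over needle at SD day 70 (3.69 on array 1, others 2.69 to 2.77) and ptPTO in shoot tip over needle at SD day 14 (0.44 on array 3, others 0.79 to 0.85). These were 4 of 118 values tested with Dixon's test, which chance passes in about 1 of 20 groups. Of 78 array measures 4 passed the same test. The share of spots not found was 32.0% on array 4 of SD day 28 (others 39.2% to 40.1%) and 33.6% on array 4 of the direct comparison at day 14 (others 31.6% to 31.7%). The correlation with the mean of the other 3 arrays was -0.11 on array 3 of the direct comparison at day 1 (others 0.17 to 0.19) and 0.63 on array 2 of the direct comparison at day 28 (others 0.53 to 0.54).

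At least 1 probe was called in every contrast between comparisons. SD minus LD differed in 17 probes at day 1, 4 at day 3, 16 at day 7, 170 at day 14, 614 at day 28 and 2051 at day 70. Low temperature differed from SD day 70 in 3953 probes, the direct comparison at day 70 from day 0 in 1145, and the tissue ratios at day 70 from day 14 in 4348 (shoot tip over needle), 2147 (stem over shoot tip) and 3619 (stem over needle). For each of these 11 counts the arrays of both sides were regrouped in 35 ways, and 1 of the 35, the real grouping, gave a count as large. This is the smallest share that 35 groupings can give, so each count passed only singly and without margin. Chance is not excluded over the 11 counts together. The highest other counts, in the same order, were 12, 0, 1, 5, 94, 1528, 1101, 475, 1, 33 and 318. For the tissue ratios the days shared no scan date, so the share of their counts due to array batches cannot be told. For shoot tip over needle the change over probes followed that of SD buds (r = 0.84), which argues against array batches alone. The small counts are weak: SD minus LD at day 1 had 17 against 12 and fell to 1 without LD array 1 or without SD array 3. At day 3 it gave 0 on its own arrays without a dye term. At day 3 489 of 11040 probes had an unadjusted p under 0.05 by limma, fewer than chance alone would give. For single comparisons the signs of 4 arrays can be assigned in only 8 ways, too few for a share under 0.05. The real and highest other counts were 182 and 2, 158 and 0, 801 and 1, 2055 and 42, 4363 and 260, 6674 and 1771, and 7637 and 833 in the SD course through low temperature, and 14 and 1, 0 and 0, 0 and 0, 150 and 0, 2991 and 4, and 4800 and 1835 in the LD course. They were 3 and 9, 43 and 0, 7 and 0, 205 and 0, 577 and 4, 1223 and 5, and 2683 and 1954 in the direct comparison, and 6551 and 0, 5082 and 16, 6377 and 0, 3183 and 1, 1706 and 1290, and 2060 and 184 between tissues. The real assignment alone gave a count as large (1 of 8), except at LD day 3 and day 7, where all 8 gave 0, and at day 0 of the direct comparison, where 2 of 8 did.

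Late change in long days resembled that in short days: ptSKN3 rose and ptSMT1 fell in both, and the log2 ratios correlated with r = 0.79 at day 70. Shared day 0 RNA would add the same covariance on every day, yet the covariance was -0.0004 at day 1 and 0.548 at day 70. Dim spots are argued against by r = 0.81 over probes above background. LD samples that held SD plants cannot be told apart from LD plants that changed like SD plants: the SD and LD arrays of day 70 did not overlap on 1342 probes, but another grouping of the same 8 arrays gave 1167, which points to a structure among the arrays. Of the 1514 probes called at day 70 in both the difference of the courses and the direct comparison, 1508 had the same sign. This cannot decide the question, since the labels do not say whether the RNA differs, and shared RNA would repeat any difference between plants. That shoot tips in long days may also slow and mature by day 70 stays open as an untested hypothesis, since the labels do not state whether LD plants set buds.

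In the tissue comparisons the authors' deposited values ran against the dye notes, with all 6 correlations between -0.94 and -0.90. A turned direction in only some arrays is argued against by the lowest correlation between arrays of a tissue comparison, 0.25, and a wrong order of the authors' values by the lowest correlation among the other columns, 0.73. Turned dye notes in all 6 comparisons are argued against by channel levels: on 16 of 16 arrays the channel called shoot tip lay closer to SD buds of the same day than the other channel. Stem over needle arrays hold no shoot tip, and their direction follows from the sum of the other ratios. Why the deposited tissue columns run the other way was not tested, and neither was a biological explanation.

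The 4 direct arrays of day 70 parted by dye orientation, and the 2683 probes called there became 883 with scaling and 0 on the 4 arrays alone, with 1954 under another assignment of signs. The fit on 4 arrays alone had no dye term, so the difference between orientations entered its spread, and the 0 partly follows from that parting. With the arrays of either orientation alone the day 70 count stayed within 1.5 times of 2683. Arrays labelled the wrong way round are argued against by correlations with the SD minus LD difference of at least 0.47 on all 4 arrays. A probe-specific dye effect common to all days is argued against by its correlation of 0.0828 with the difference between orientations. Scan date as the cause is argued against by 1 scan date shared by both orientations. What the 2 orientations differ in could be the plants themselves, since each orientation holds other replicates; this was not tested.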

How the results depend on the processing

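The fits without the 2 tissue arrays with most spots not found, without the 2 arrays with misnamed blocks, with the direct day 70 arrays of each dye orientation alone and with the tissue direction of the authors' values were chosen after seeing the data, and the other settings before the data were examined. Of 135 calls of gene-named probes with the same sign on all arrays, the settings that keep all replicates gave 1010 values, of which 934 kept the call, 76 lost it and 0 turned. Probes above background held only 115 of the 135 calls, and calls on the other probes dropped out without counting as lost. Those probes are not marked in the results above. Fits without an array kept 511 of 608 and lost 97. Counts within 1.5 times are taken as unmoved. Median centring left 36 of the 37 counts unmoved, probes above background 36, no background correction 33, the scan date block 32, no dye term 27, each comparison on its own arrays 12 and scaling between arrays 9. The misnamed arrays and the turned tissue direction moved none of the counts they bear on, and the turned direction exchanges up and down in the tissue comparisons by construction. The cause was not tested except where stated. No paired analysis was possible because each GEO sample is a whole comparison and the labels number no arrays across comparisons. The gene list alternatives were not run, since the lists matched no probe.

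Scaling forces an equal spread on every array of an experiment, which by construction raises comparisons of small spread and lowers those of large spread. It gave, at days 1, 3, 7 and 14, 710, 1121, 2372 and 3187 in the SD course, with 4225 at day 70 and 4357 after low temperature. It gave 16, 22, 374 and 2272 at LD days 3, 7, 14 and 70. It gave 77 (52 up, 25 down; main 3 up, 0 down), 160 (82 and 78; main 27 and 16), 143 (84 and 59; main 6 and 1), 325 and 883 in the direct comparison at days 0, 1, 3, 7 and 70. Between tissues it gave 4211 for shoot tip over needle at day 14, and 2968 for stem over shoot tip and 3703 for stem over needle at day 70. SD minus LD became 179, 227 (89 up, 138 down; main 4 and 0), 527 (286 and 241; main 12 and 4), 747 (354 and 393; main 59 and 111), 231 (110 and 121; main 230 and 384) and 94 from day 1 to day 70. Low temperature minus SD day 70 became 491, direct day 70 minus day 0 274, and day 70 minus day 14 2753 for shoot tip over needle and 1910 (490 up, 1420 down; main 1489 and 2130) for stem over needle.

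With each comparison on its own arrays and no dye term, the spread rested on fewer arrays and took in dye effects. SD days 1, 3, 7 and 14 then gave 4, 50, 265 and 1275. LD days 1, 14, 28 and 70 gave 0, 15, 1828 and 1639, and direct days 1, 7, 14, 28 and 70 gave 0, 60, 70, 663 and 0. Stem over needle gave 4077 at day 14 and 1227 at day 70, stem over shoot tip 708 at day 70. SD minus LD gave 1, 0, 7, 13, 41 and 270, low temperature minus SD day 70 2405, direct day 70 minus day 0 120, and stem over needle day 70 minus day 14 2222. With all arrays but no dye term, SD days 1, 3 and 7 gave 114, 96 and 427, LD day 14 76, and direct days 1 and 7 24 and 134. SD minus LD at days 1, 3, 14 and 28 then gave 2, 2, 81 and 400. No background correction gave 116 at SD day 1, 66 at LD day 14, 5 at direct day 0 and 3 for SD minus LD at day 1. Median centring gave 74 at LD day 14. Probes above background gave 0 at direct day 0. The scan date block gave 234 at LD day 14, 28 and 911 at direct days 0 and 14, and 27 and 26 for SD minus LD at days 1 and 7. Its consensus correlations were negative, so the block did not guard against a batch effect, and all 5 counts that it moved rose. The joint tissue fit gave 3562 for stem over needle at day 70 and 3651 for stem over shoot tip, day 70 minus day 14. Without the 2 tissue arrays stem over shoot tip at day 70 gave 835 (289 up, 546 down; main 763 and 943). The direct day 70 minus day 0 count was 1779 with the swapped and 2539 with the unswapped arrays alone.

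Leaving out each array in turn gave the following ranges. SD days 1, 3, 7 and 14 ranged over 67 to 200, 24 to 125, 123 to 535 and 907 to 1881. LD days 1, 3, 7 and 14 ranged over 5 to 8, 0 to 1, 0 to 1 and 0 to 144. Direct days 0, 1, 3, 7, 14 and 28 ranged over 0 to 19, 5 to 28, 0 to 6, 30 to 128, 236 to 484 and 584 to 938. At day 70 shoot tip over needle ranged from 1849 to 2599 and stem over shoot tip from 819 to 2191. SD minus LD at days 1, 3, 7, 14 and 28 ranged over 1 to 19, 2 to 8, 2 to 20, 30 to 142 and 182 to 711, and direct day 70 minus day 0 from 744 to 1340. The remaining counts stayed within 1.5 times. Counts moved by over 1.5 times without these arrays. SD day 1 gave 91 without array 3 and 67 without array 4. SD day 3 gave 31, 24 and 75 without arrays 2, 3 and 4. SD day 7 gave 123, 234 and 251 without arrays 1, 3 and 4. SD day 14 gave 1018 and 907 without arrays 1 and 2. LD day 1 gave 6, 8, 7 and 5 without arrays 1 to 4, and LD days 3 and 7 gave 1 without array 2 and 1 without array 3. LD day 14 gave 0, 9 and 0 without arrays 1, 3 and 4. Direct day 0 gave 1, 19, 1 and 0 and day 1 gave 28, 28, 10 and 5 without arrays 1 to 4. Direct day 3 gave 0 without array 2 and 0 without array 4. Direct day 7 gave 30, 128, 64 and 108 without arrays 1 to 4. Direct day 14 gave 236 and 254 without arrays 2 and 4, and day 28 gave 685, 584 and 689 without arrays 1, 2 and 3. Shoot tip over needle at day 70 gave 1849 and 2058 without arrays 1 and 3, and stem over shoot tip 819 and 903 without arrays 3 and 4. SD minus LD at day 14 gave 35 and 30 without SD arrays 1 and 2, and 100, 81, 78 and 84 without LD arrays 1 to 4. At day 28 it gave 307 and 182 without SD arrays 1 and 3, and 296 and 371 without LD arrays 1 and 2. At days 1, 3 and 7, with 17, 4 and 16 probes, 5, 5 and 4 of the 8 fits moved the count. Direct day 70 minus day 0 gave 744 without array 1 of day 0 and moved likewise without array 2 of day 0.

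The correlation of direct with indirect differences, 0.54, 0.53, 0.58, 0.62, 0.66 and 0.84 from day 1 to day 70, became 0.44, 0.43, 0.52, 0.52, 0.57 and 0.78 as Spearman's rho, 0.60, 0.56, 0.63, 0.65, 0.71 and 0.86 over probes above background, and 0.52, 0.48, 0.57, 0.56, 0.64 and 0.83 as Spearman's rho over those probes.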

Other observations

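The groups of probes described here, and their tests, were chosen after the data were seen, and their tissue names follow the dye notes. Probes lower in needle than in shoot tip and stem at day 14 were the only 1 of the 6 groups whose difference of SD minus LD at day 70 passed the test with an estimated correlation. Of these 954 probes, 719 fell and 73 rose at SD day 70, with a median log2 ratio of -1.23 (camera, adjusted p = 0.0107 with an estimated correlation). In the difference of SD minus LD at day 70, 324 were lower and 4 higher in SD, with a median of -0.60 (adjusted p = 0.0403 with an estimated correlation). The direct comparison at day 70 had 376 lower and 14 higher, with a median of -0.48 (adjusted p = 4.34e-19 with the preset correlation, and adjusted p = 0.205 with an estimated correlation).

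Between SD day 70 and low temperature, the largest median shifts were in groups defined by stem and needle. Of 498 probes lower in stem than in both other tissues, 298 were lower and 24 higher after low temperature than at SD day 70, with a median of -0.76 (adjusted p = 1.22e-20 with the preset correlation, and adjusted p = 0.282 with an estimated correlation). Of 451 probes higher in needle, 314 rose and 30 fell at SD day 70, with a median of 0.65 (adjusted p = 2.63e-15 with the preset correlation, and adjusted p = 0.106 with an estimated correlation). After low temperature 218 of those 451 were lower than at SD day 70 and 39 higher, with a median of -0.57 (adjusted p = 6.93e-13 with the preset correlation, and adjusted p = 0.282 with an estimated correlation). The calls of this paragraph were lost with an estimated correlation.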
